A study of Mus musculus with 54 samples.

How the data were processed

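Mouse embryonic stem cells of the 129/Ola strain were differentiated through embryoid bodies toward heart muscle, and 5 targets were profiled by ChIP-seq at 4 stages. The labels list 54 libraries, of which 46 come with a list of enriched regions and 8 are whole cell extract without one. The reads were not used here. Per the labels, reads were aligned with Bowtie to the mm9 genome, without a stated version, and replicates are biological. The region caller and its settings are not stated.

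Each deposited list gives the position of every enriched region, its length, its highest point and its totals. Lengths in the deposited lists are in bases, a unit recorded as other, and equal end minus start, and positions are printed with the first base of a region as its start, 1 above the listed start. The peak heights and the target and background totals of the deposited lists were taken as signal, not as counts of reads, since the values behave as sums over 25-base bins and the caller is not stated. The background totals hold decimals and were scaled by the authors in a way that is not stated. The lowest ratio of target to background in a list was 5 to 5.06, regions lay at least 225 bases apart, and the minimum peak height differed between lists, from 9 to 39. One list has no header and was read with the column order of the others, after a check of its values. No depth is given, so no counting interval could be had for any library.

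Libraries were grouped by target and stage as labelled. The cell type label of the H3K27ac CM libraries names embryonic stem cells, while their title, source and time point name cardiomyocytes, and they were grouped as CM. Comparisons used chromosomes 1 to 19 and X, with 1590704 regions over all lists. Regions of a library were merged, and regions of a mark were joined over its libraries into a union. An overlap of at least 1 base counted as presence. No background control was compared, since the whole cell extract libraries have no region list and the background totals stand only inside called regions.

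Stages were compared by exact permutation of the stage labels, on log2 of the number of regions and of the covered length (two-sided by construction, as a sum of squares between stages) and on the difference of the mean Jaccard index within and between stages (one-sided). The p-values were adjusted by the Benjamini-Hochberg method over the 5 marks. With 2 libraries per stage there are 105 arrangements and the smallest p is 0.0095, and with 3 per stage there are 15400. Gained, lost, stage-concordant and bivalent regions required the same call in every library of a stage. A distal region was one with H3K4me1 in every library of a stage and no overlap with H3K4me3 in any, active with H3K27ac in every library and H3K4me1 alone with H3K27ac in none. Earlier H3K4me1 and nearness within 50 kb were compared by two-sided Fisher exact tests, with 95% intervals of the odds ratio. The shares at randomly placed regions are means of 20 placements. The counts of stage-concordant regions were set against 100 seeded regroupings of the libraries. The regions named are the 5 longest gained and the 5 longest lost between ESC and CM for each mark, by a rule fixed before the data were examined.

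Several comparisons had been laid out on genes, with 16 gene lists. The annotation at hand is of another genome build than the lists, and positions were not carried between builds, so these comparisons were made on regions instead, a choice made after the files were seen. The tests of gene lists, windows around start sites and distances to start sites were not run. The comparison of marks that changed together was also added after the files were seen.

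Alternatives were an equal number of top regions by peak height in every library of a mark, regions closer than 1 kb merged, regions under 500 bases left out, a majority of libraries in place of all, an overlap of at least 50% of the shorter region, another similarity measure, a distance of 20 kb, the nearest H3K4me3 region alone, replicate numbers as a block, and each replicate number left out in turn. The code that calls gained regions was checked on simulated data. Of 200 gained regions planted among 209814, 46%, 83% and 100% were recovered with 80%, 95% and 100% detection per library. Independent calls give 51.2%, 85.7% and 100% by construction. Without any stage effect, 5% of 1000 simulated data sets fell under 0.05 in the test on numbers and 3.7% in the test on overlap. Those data sets held independent random values, unlike Jaccard indices of shared libraries, so they check the code alone. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.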

Results

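Chromatin was mapped by ChIP-seq while mouse embryonic stem cells of the 129/Ola strain were directed to become heart muscle cells in culture. Libraries were made at 4 stages, embryonic stem cells (ESC, day 0), mesoderm (MES, day 4), cardiac precursors (CP, day 5.3) and cardiomyocytes (CM, day 10). The 5 targets were H3K4me1, found at enhancers and flanking promoters, H3K27ac, found at active enhancers and promoters, H3K4me3, found at promoters, H3K27me3, laid down by the Polycomb repressor, and RNA polymerase II phosphorylated on Ser5 (RNAPII Ser5P), the form found near the start of transcription. H3K4me1 had 3 libraries per stage, H3K27ac and H3K4me3 had 2 per stage, H3K27me3 had 2 in ESC and 3 at each later stage, and RNAPII Ser5P had 1 in ESC and 2 at each later stage. The values are lists of enriched regions, called by the authors in each library separately, for 46 libraries. Read depth is not given in the lists, so the depth of each library is unknown.

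The number and the covered length of the regions were compared between stages. ESC had the most H3K4me3 regions, with a mean of 48310 ± 8794 (SD, n = 2), against 25543 ± 4719 in MES, 24498 ± 4574 in CP and 23700.5 ± 2757 in CM (n = 2 each). These regions covered 45.6 ± 5.14 Mb in ESC and 26.4 ± 2.98 Mb in CM (SD, n = 2 each). The median ratio of target to background was 9.47 and 9.42 in the ESC libraries of H3K4me3, below the 16.3 to 23.0 of the 6 later ones. RNAPII Ser5P regions numbered 48837 in the single ESC library and 12068.5 ± 1042 in CM (SD, n = 2). H3K27me3 regions numbered 6312.5 ± 4328 in ESC (SD, n = 2), 14659 ± 4731 in MES, 22400 ± 13881 in CP and 11779 ± 8778 in CM (SD, n = 3 each). H3K4me1 covered 38 ± 11.1 Mb in ESC, 53.9 ± 3.66 Mb in MES, 45.4 ± 17.9 Mb in CP and 36.4 ± 2.66 Mb in CM (SD, n = 3 each).

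None of the 5 marks passed the test for a difference between stages in number of regions or in covered length. In exact permutation tests of the stage labels, the lowest p for the number was 0.0762, for RNAPII Ser5P (n = 7), with an adjusted p of 0.286 over the 5 marks. H3K4me3 had p = 0.114 for the number and 0.0571 for the covered length, with adjusted p of 0.286 and 0.262 (exact permutation, n = 8). Libraries of a single stage differed widely, from 33958 to 83818 H3K4me1 regions in ESC and from 2929 to 20484 H3K27me3 regions in CM. Each list also has its own minimum peak height, from 9 to 39, so numbers of regions are not on a common scale across libraries.

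**Figure D1:**
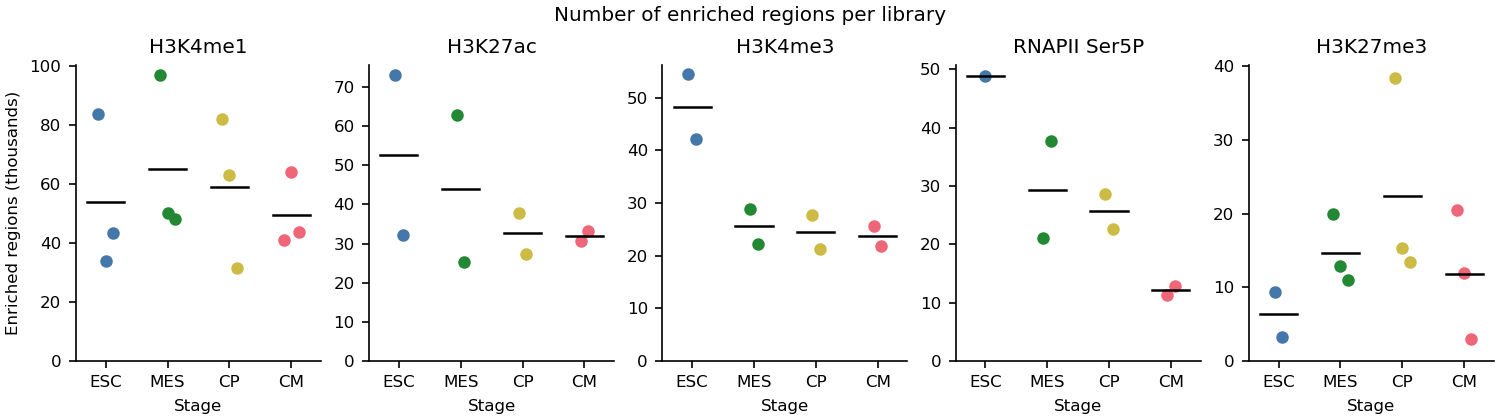
Number of enriched regions (vertical axis, in units of 1000, starting at 0, with its own scale per panel) in each library at the 4 stages (horizontal axis), 1 panel per mark; each point is a library and the horizontal lines are stage means. Both ESC libraries of H3K4me3 (42092 and 54528) lie above the 6 later ones, the highest of which has 28880, while H3K4me1 libraries of a single stage spread from 31571 to 82089 in CP.

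The next comparison asked whether libraries of a stage had their regions in the same places. H3K4me1 and H3K27ac marked different sites at different stages. The mean Jaccard index, the share of covered bases that 2 libraries have in common, was 0.389 for H3K4me1 libraries of the same stage and 0.163 for libraries of different stages. For H3K27ac the values were 0.499 and 0.313. ESC stood furthest from CM, with a mean index of 0.0825 for H3K4me1, while CP and CM had 0.249 and MES and CP 0.263. ESC replicate 1 of H3K4me1 had a lower index with ESC replicate 2 (0.190) than with MES replicate 1 (0.237). H3K4me3 had the highest values, with 0.715 within and 0.600 between stages. Its ESC libraries had 0.521, 0.494 and 0.474 with MES, CP and CM, whereas the 3 later stages had 0.666 to 0.742 with each other.

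Grouping by stage passed the test for H3K4me1 (p = 6.49e-05, the smallest that the permutations can give, adjusted p = 0.000325, n = 12) and for H3K27ac (p = 0.0095, also the smallest possible, adjusted p = 0.0238, n = 8), in one-sided exact permutation tests. It did not pass for H3K4me3 (p = 0.0476, adjusted p = 0.0726, n = 8), H3K27me3 (p = 0.0581, adjusted p = 0.0726, n = 11) or RNAPII Ser5P (p = 0.162, adjusted p = 0.162, n = 7) in the same exact permutation tests. These tests take no account of replicate number, which as a block brought these marks past the threshold, as given further below. RNAPII Ser5P lists differed by number, with minimum peak heights of 9 to 13 in number 1 and 22 to 28 in number 2. For this mark, MES replicate 2 had an index of 0.394 with ESC replicate 2 and 0.205 with MES replicate 1. With the share of regions of the smaller list that overlap the larger one in place of the Jaccard index, H3K4me3 and H3K27me3 passed, with adjusted p of 0.0119 and 0.000487. For H3K27me3 the outcome also turned on single replicates, with an adjusted p of 0.0238 without replicate 3, 0.381 without replicate 2, and 0.352 with the difference in the opposite direction without replicate 1 (exact permutation).

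**Figure D2:**
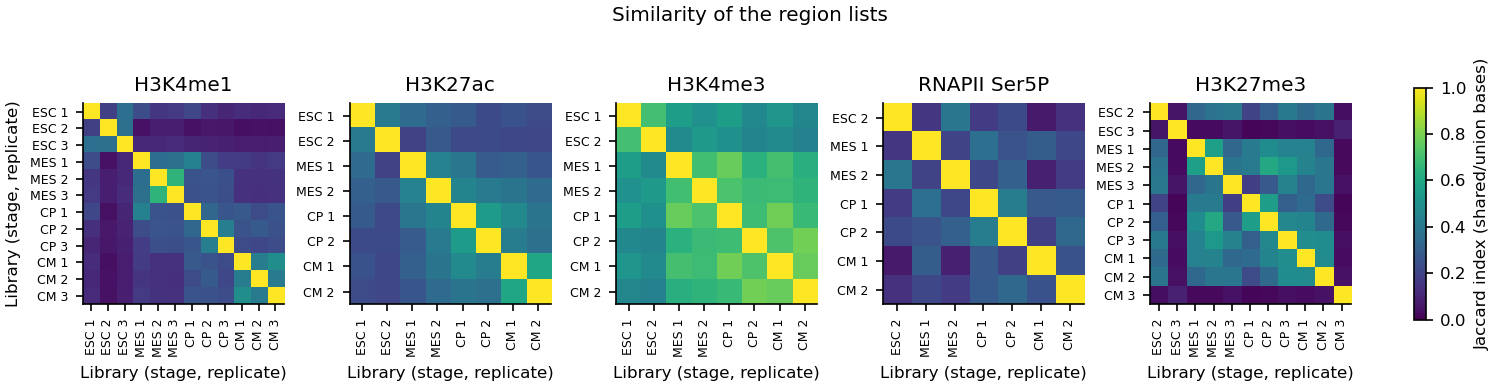
Jaccard index of covered bases (color scale) for every pair of libraries of a mark, 1 panel per mark, with libraries in rows and columns ordered by stage and replicate. The H3K4me1 and H3K27ac panels show blocks of higher values along the diagonal, with stage means of 0.389 and 0.499 within stages, and in the H3K4me3 panel the ESC libraries stand apart from the later ones at 0.474 to 0.521.

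Regions gained and lost between stages show where the calls differed between libraries of stem cells and of later stages. A region was counted as gained when no library of the earlier stage and every library of the later stage had it, and as lost in the opposite case. Between ESC and CM, 11023 H3K4me1 regions were gained and 8902 were lost, which are 55.5% of the regions present in every CM library and 65.4% of those present in every ESC library. H3K27ac gained 6941 regions (34.6%) and lost 12090 (53.9%). H3K4me3 gained 922 (4.94%) and lost 16321 (46.5%). RNAPII Ser5P gained 836 (14.6%) and lost 35362 (81.6%), the ESC side resting on a single library. H3K27me3 gained 206 (17.7%) and lost 167 (12.6%).

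The first step, from ESC to MES, had the largest changes for H3K4me1, H3K27ac and H3K4me3 among the 3 steps. H3K4me1 gained 10750 and lost 6693 regions from ESC to MES, gained 3021 and lost 4747 from MES to CP, and gained 4058 and lost 3636 from CP to CM. H3K4me3 lost 15599 regions from ESC to MES and changed at 809 and 949 regions in the later steps. With an equal number of top regions by peak height in every library, H3K4me3 gained 1758 and lost 3078 from ESC to MES. H3K27me3 gained 1186 regions and lost 52 from ESC to MES, then gained 11 and lost 933 from CP to CM. Without ESC replicate 3 and CM replicate 3 of H3K27me3, which hold few regions (3252 and 2929), it gained 1254 and lost 1737 in the first step, so that losses outnumbered gains. It gained 439 and lost 935 in the last. ESC then rests on 1 library of this mark. A first-step loss asks for a call in that library alone, and a gain for calls in all 3 MES libraries, so these losses and gains are not on a common footing. The losses of H3K27me3 in the last step were 2151 without replicate 1, 1577 without replicate 2 and 4050 without replicate 3 of any stage. H3K27ac gained 4185 and lost 9540 from ESC to MES, gained 3475 and lost 4250 from MES to CP, and gained 4788 and lost 4006 from CP to CM. In the later steps the balance of gains and losses turned with single replicates. H3K4me1 gained 8080 and lost 6690 from MES to CP without replicate 3, and from CP to CM it gained 6015 and lost 12053 without replicate 3 and gained 6361 and lost 6685 without replicate 2. Without replicate 2, H3K27ac gained 11117 and lost 17008 from CP to CM, and H3K4me3 gained 3260 and lost 5095. H3K27ac gained 12590 and lost 19215 from ESC to MES without replicate 1 and gained 31748 and lost 44060 without replicate 2, and from MES to CP it gained 10321 and lost 10584 without replicate 1 and gained 12885 and lost 37097 without replicate 2. The low number of later H3K4me3 changes also rested on both replicates, with 4745 gained and 5164 lost from MES to CP without replicate 2, 1265 gained and 2633 lost without replicate 1, and 2350 gained and 1500 lost from CP to CM without replicate 1. In the first step, H3K4me3 lost 31159 regions without replicate 2, H3K4me1 gained 22003 and lost 11686 without replicate 1 and gained 13852 and lost 13377 without replicate 2, and H3K27me3 gained 3210 and lost 1752 without replicate 3 of any stage.

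These counts carry no test per region, since an exact permutation of 2 or 3 libraries per stage cannot reach 0.05 at a single region. With an equal number of top regions by peak height in every library of a mark, H3K27ac gained 6949 and lost 6775, H3K4me3 gained 2199 and lost 3349, RNAPII Ser5P gained 1597 and lost 5245, and H3K4me1 gained 8276 and lost 4608. Replicate 3 of H3K27me3 decided that mark's counts, with 2048 gained and 2433 lost without it, 666 and 369 without replicate 2, and 204 and 271 without replicate 1. Without replicate 2 or 3, ESC has a single library of this mark. Leaving out a replicate also raised other counts, to 21109 H3K4me1 regions gained without replicate 1 and 19003 lost without replicate 2, to 21337 and 13862 H3K27ac regions gained and 20287 and 56277 lost without replicates 1 and 2, to 2089 and 4062 H3K4me3 regions gained without replicates 1 and 2, to 32533 H3K4me3 regions lost without replicate 2, and to 4312 RNAPII Ser5P regions gained without replicate 1.

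**Figure D3:**
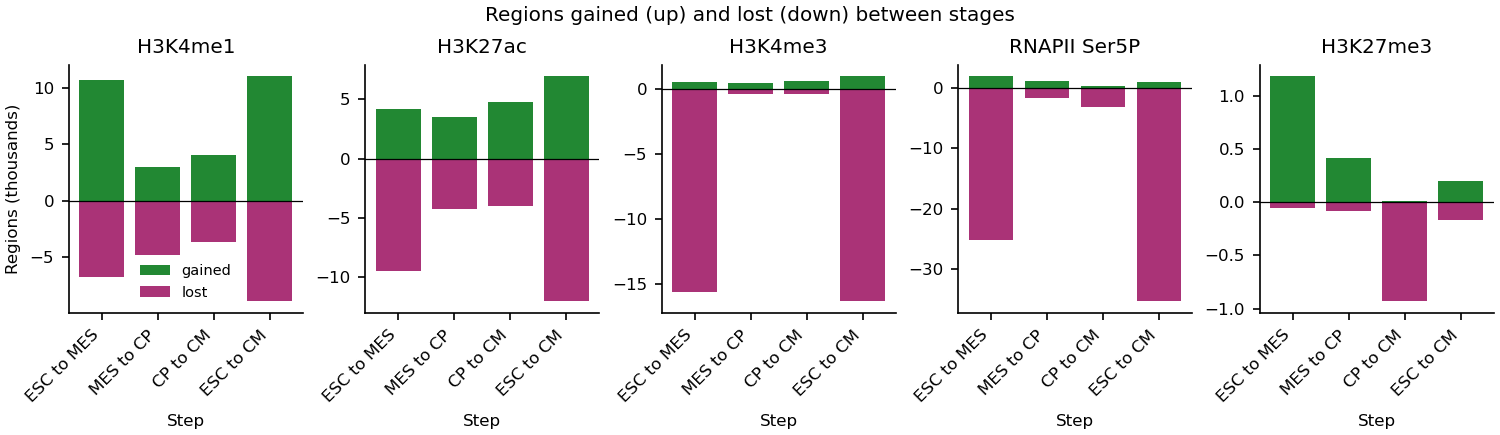
Number of regions in units of 1000, gained (bars above 0) and lost (bars below 0) for each mark, 1 panel per mark, at the steps ESC to MES, MES to CP, CP to CM and ESC to CM (horizontal axis); each panel has its own vertical scale. H3K4me3 losses fall in the first step (15599 of its regions), and H3K27me3 gains 1186 regions in the first step and loses 933 in the last. Its first-step losses are 1737 without ESC replicate 3, which leaves 1 ESC library.

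The longest changed regions between ESC and CM, 5 gained and 5 lost per mark, were examined across all marks, with positions in the mm9 build. The longest gained H3K27ac region, chromosome 16 from 24486226 to 24503375 (17150 bases), had no H3K27ac in ESC and had it in both libraries of each later stage. H3K4me1 was absent there in ESC and present in all 3 libraries of MES, CP and CM, and RNAPII Ser5P appeared in 1 CP and 2 CM libraries. On chromosome 7, the gained H3K4me1 region from 119894951 to 119908200 (13250 bases) held the gained H3K27ac region from 119895501 to 119908050 (12550 bases), with both marks in every library from MES on. The gained H3K27ac region on chromosome 10 from 53048426 to 53060600 (12175 bases) took up H3K4me1 and H3K27ac in every CP library and H3K4me3 and RNAPII Ser5P in both CM libraries only.

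Among H3K4me3 gains, the region on chromosome 14 from 55579301 to 55585500 (6200 bases) lay inside the longest gained RNAPII Ser5P region, from 55547401 to 55593725 (46325 bases). Both had their mark in neither ESC nor MES and in every CP and CM library. A further gained H3K4me3 region lay close by on the same chromosome, from 55608901 to 55614050 (5150 bases), with H3K27ac and RNAPII Ser5P in both libraries of CP and of CM and in none before. The longest gained H3K4me3 region, chromosome 9 from 75622801 to 75629050 (6250 bases), had the mark in every library from MES on and no RNAPII Ser5P in any library.

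Losses of several marks overlapped at 2 places among the regions named. On chromosome 16 the longest lost H3K27ac region, from 22396176 to 22419025 (22850 bases), held the longest lost H3K4me3 region, from 22404676 to 22414600 (9925 bases), and overlapped the lost RNAPII Ser5P region from 22383551 to 22415425 (31875 bases). H3K4me3 and RNAPII Ser5P were called there only in ESC, while H3K27ac stayed in both libraries of MES and of CP and was absent in CM. On chromosome 13 the longest lost RNAPII Ser5P region, from 98251076 to 98291725 (40650 bases), overlapped a lost H3K27ac region from 98251451 to 98265450 (14000 bases), where H3K27ac was in 2 ESC libraries, 1 MES library and none later. The longest lost H3K4me1 region, chromosome 17 from 30731126 to 30748925 (17800 bases), kept H3K27ac and H3K4me3 in both libraries of all 4 stages.

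The longest H3K27me3 gains lay where H3K27ac was present in ESC and absent in CM. The longest gain, chromosome 3 from 34546926 to 34572275 (25350 bases), had H3K27me3 in no ESC library and in all 3 libraries of each later stage, while H3K27ac was called in 2 ESC libraries, 1 MES library and none later. H3K4me3 stayed in both libraries of all 4 stages there. All 5 gained regions had H3K27ac in both ESC libraries and in no CM library. The longest loss, chromosome 8 from 59794801 to 59832500 (37700 bases), had H3K27me3 in every library of ESC, MES and CP and in none of CM, with RNAPII Ser5P absent in ESC and in both libraries of each later stage. All 5 lost regions had H3K27ac in both CM libraries, and 4 of them had it in fewer than 2 ESC libraries. No annotation of this genome build was used, so these regions carry no gene names.

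Stage-concordant regions, called in every library of at least 1 stage and in no library of at least 1 other, measured how much of each mark followed the stages. There were 37961 of 209814 H3K4me1 regions, 29731 of 130719 H3K27ac regions, 18916 of 63350 H3K4me3 regions, 39713 of 79111 RNAPII Ser5P regions and 3243 of 47953 H3K27me3 regions. An equal number of top regions per library lowered them to 23873 for H3K4me1, 6971 for H3K4me3, 9074 for RNAPII Ser5P and 1183 for H3K27me3. Without replicate 1 they were 62302 for H3K4me1, 59249 for H3K27ac and 63272 for RNAPII Ser5P, without replicate 2 they were 110327 for H3K27ac, 44562 for H3K4me3 and 6269 for H3K27me3, and without replicate 3 they were 10769 for H3K27me3.

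Bivalent regions carry both H3K4me3 and H3K27me3, a state known in stem cells at promoters of developmental genes. Of 35685 H3K4me3 regions called in both ESC libraries, 1123 (3.15%) also had H3K27me3 in both ESC libraries of that mark. Most of these kept both marks in every library of MES (958 regions, 85.3%) and of CP (851 regions, 75.8%). In CM, 424 (37.8%) had both marks in every library, 121 (10.8%) had H3K4me3 alone, 31 (2.76%) had H3K27me3 alone, 8 had neither and 539 (48%) had calls that differed between libraries. Per library, H3K27me3 was called at 93.9 ± 4.59% of the bivalent regions in MES, 93.1 ± 3.66% in CP and 71.1 ± 22.8% in CM (SD, n = 3 each), and H3K4me3 at 97.5 ± 2.14%, 92.0 ± 6.55% and 91.4 ± 4.60% (SD, n = 2 each).

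A difference in the H3K27me3 share between MES, CP and CM did not pass correction over 8 tests, with p = 0.0286 and adjusted p = 0.229 (exact permutation, n = 3 per stage). The other 7 tests, those of H3K4me3 among them, cannot go below p = 0.0667 by exact permutation and could not have passed. Replicate 3 of H3K27me3 set the number of bivalent regions, which was 3568 (10.0%) without it, with H3K27me3 in ESC then taken from replicate 2 alone. Of those, 2024 (56.7%) had both marks in CM and 664 (18.6%) had H3K4me3 alone, and H3K27me3 was called at 72.2 ± 6.60% in CM against 90.2 ± 3.49% in MES (SD, n = 2 each). These are shares of a larger set of regions than the 1123, so the CM shares of the sets are not on a common footing. The exact permutation test on H3K27me3 at the larger set gave p = 0.2. An equal number of top regions per library gave 744 bivalent regions, regions of at least 500 bases gave 63, and 188 regions had H3K4me3 alone in CM without replicate 1.

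**Figure D4:**
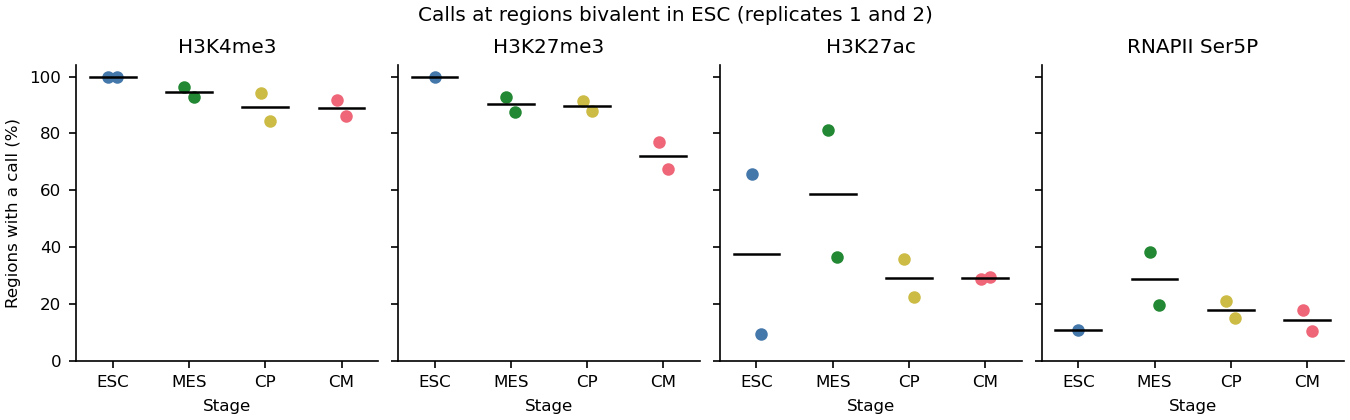
Share in percent (vertical axis, from 0) of the 3568 regions bivalent in ESC without replicate 3 at which H3K4me3, H3K27me3, H3K27ac and RNAPII Ser5P (panels) were called in each library of replicates 1 and 2, by stage (horizontal axis); points are libraries and horizontal lines are stage means. The H3K27me3 mean is 90.2% in MES and 72.2% in CM, while H3K4me3 has 94.6% and 88.9%, and ESC is at 100% for both marks by the way the regions were chosen. H3K27me3 in ESC is 1 library here.

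Active distal regions, H3K4me1 regions away from H3K4me3 that also carry H3K27ac, were compared because they mark enhancers in use. Few regions were called active at more than 1 stage, under a rule that asks for the call in every library of each stage. Counting regions with H3K4me1 and H3K27ac in every library of a stage and H3K4me3 in none, there were 2016 in ESC, 2805 in MES, 2313 in CP and 4267 in CM. Of the H3K4me1 regions in every library, 44.9% were distal in ESC, against 58.8% in MES, 60.8% in CP and 66.4% in CM. ESC also had the most H3K4me3 regions to overlap, so its counts and those of later stages are not on a common footing. Of the 10115 merged regions, 9043 were active at a single stage, 3448 (34.1%) of them in CM alone, 2284 (22.6%) in MES alone, 1926 (19%) in ESC alone and 1385 (13.7%) in CP alone, and 2 were active at all 4 stages. Of the regions active in ESC, 2.03% were active in MES and 1.64% in CM, whereas 28.1% of those active in CP were active in CM and 16.2% in MES.

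Enhancer marks were mostly not called later at the regions active in every ESC library. The SDs below are over the libraries in which the marks were called, and not over the choice of regions. H3K27ac was called at 7.56 ± 0.526% of them in MES, 4.91 ± 0.421% in CP and 4.69 ± 1.16% in CM (SD, n = 2 each), and H3K4me1 at 18.4 ± 1.02%, 12 ± 3.11% and 7.74 ± 0.667% (SD, n = 3 each). Of the regions active in CP, 50.5 ± 1.53% had H3K27ac in a CM library (SD, n = 2) and 68 ± 4.77% had H3K4me1 (SD, n = 3). Looking back from the regions active in CM, H3K27ac was called at 16.3 ± 9.88% in ESC, 24.1 ± 11.5% in MES and 41.7 ± 11.6% in CP (SD, n = 2 each), and H3K4me1 at 16.0 ± 9.71%, 30.5 ± 8.98% and 55.7 ± 12.7% (SD, n = 3 each).

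Sets of active regions made from a single replicate number shared 51.8% of the smaller set within a stage (35.8% to 67.9%, 4 pairs) and 15.0% between stages (1.88% to 35%, 24 pairs). The difference of 36.8 percentage points had p = 0.0095 in an exact permutation test, the smallest that 105 arrangements of the 8 sets can give. The ESC sets differed from each other in this. With sets of later stages, that of number 1 shared 5.56% to 12.3% of the smaller set, and that of number 2 shared 1.88% to 4.40%. A difference between stages in the share of distal H3K4me1 regions that were active did not pass its test, with shares of 30.1 ± 0.0275% in ESC, 23.3 ± 7.42% in MES, 18.0 ± 2.46% in CP and 28.3 ± 2.67% in CM (SD, n = 2 each, exact permutation p = 0.229). The numbers of active regions rose when a replicate was left out, to 4569 and 6844 in ESC, 5742 and 7903 in MES and 4526 and 4600 in CP without replicates 1 and 2, to 3496 in CP without replicate 3 and to 8481 in CM without replicate 1.

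**Figure D5:**
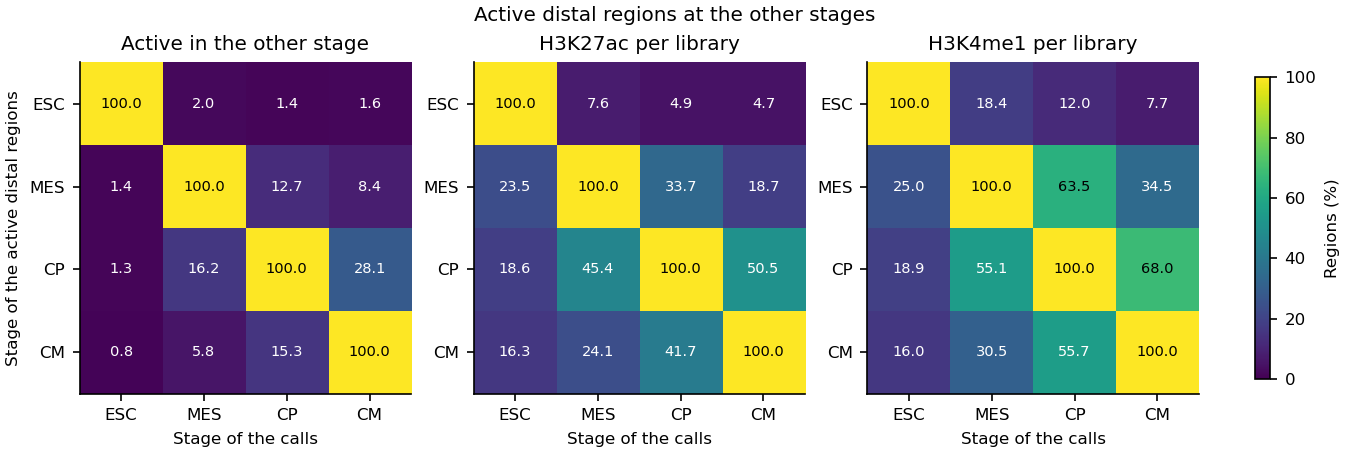
Share in percent (color scale and printed values) of the active distal regions of a stage (vertical axis) that at each stage (horizontal axis) were active in the left panel, or carried H3K27ac or H3K4me1 in the middle and right panels as a mean over libraries; the diagonal is 100% by definition. In the left panel ESC regions have 1.44% to 2.03% at later stages and CP regions 28.1% in CM, and in the right panel H3K4me1 is at 55.7% of CM regions in CP.

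Newly active distal regions were examined for H3K4me1 at the stage before, a mark that can precede H3K27ac at enhancers. A region was newly active when it did not meet the full rule for activity at the stage before. H3K27ac could thus already be called there. Of all regions active in MES, CP and CM, 33.3%, 60.2% and 53.3% had H3K27ac in at least 1 library of the stage before. The comparison therefore does not settle whether H3K4me1 came before H3K27ac. Earlier H3K4me1 in all libraries was no more common at newly active regions than at regions with H3K4me1 alone at the same stage. From ESC to MES, 9.72% of 2767 newly active regions had it, against 9.52% of 6868 regions with H3K4me1 alone (odds ratio 1.02, 95% interval 0.881 to 1.19, Fisher exact p = 0.760). From MES to CP it was 30.5% of 1939 against 42.9% of 5678 (odds ratio 0.584, 95% interval 0.523 to 0.652, Fisher exact p = 2.34e-22), and from CP to CM 25.2% of 3615 against 28.1% of 6496 (odds ratio 0.859, 95% interval 0.783 to 0.942, Fisher exact p = 0.00127, adjusted p = 0.00255). Randomly placed regions had earlier H3K4me1 at 1.93%, 3.53% and 2.08% in the 3 steps, so both groups lay above that background.

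Regions are not independent of each other, and across single replicate numbers the shares at newly active regions were 21.1 ± 12.5%, 31.1 ± 5.01% and 37.9 ± 8.84% (SD, n = 2 each), against 18.3 ± 8.77%, 43.9 ± 7.26% and 41.9 ± 10.3% at regions with H3K4me1 alone. With earlier H3K4me1 in at least 1 library the odds ratio from ESC to MES was 1.61, an excess past the threshold. It was 0.710 from MES to CP and 1.08 from CP to CM, where the direction changed. Length was not stratified under this rule, although newly active regions in MES were longer (median 2050 against 1100 bases). The call from CP to CM also ended without replicate 3 (odds ratio 0.931), and with regions already active in CP left out of the comparison (0.992). The step from ESC to MES had an odds ratio of 0.962 without replicate 1, 0.953 without ESC replicate 1 of H3K4me1, and 0.720 with an equal number of top regions. Over the whole course from ESC to CM, 5.46% of 4233 newly active regions and 6.54% of those with H3K4me1 alone had it (odds ratio 0.825, 95% interval 0.699 to 0.973, Fisher exact p = 0.0233, adjusted p = 0.0311). That call ended without replicate 3 (0.898), with replicate numbers as a block (0.886) and with regions active in ESC left out of the comparison (0.893). The ratio was 1.04 with earlier H3K4me1 in at least 1 library.

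Newly active distal regions were then set against gained H3K4me3 regions, to ask whether they lay near each other. No annotation was used, so the gained H3K4me3 regions are not known to be promoters. Of the 922 H3K4me3 regions gained between ESC and CM, 263 (28.5%) had a distal region newly active in CM within 50 kb. The share was 18.4% for 17239 H3K4me3 regions kept in both stages and 22% for the 16321 lost. The odds ratio of gained against kept was 1.77 (95% interval 1.53 to 2.05, two-sided Fisher exact p = 4.03e-13), and of gained against lost 1.42 (95% interval 1.22 to 1.64, Fisher exact p = 6.14e-06). With the libraries of replicate number 1 or 2 alone, the odds ratio of gained against kept was 1.93 or 1.51. With each newly active region assigned to its nearest H3K4me3 region at any distance, that odds ratio was 3.05 (Fisher exact p = 1.13e-31). The 50 kb limit was not applied there, so the value is not on a common scale with the others. With an equal number of top regions in every library the association was absent (odds ratio 0.987, Fisher exact p = 0.855).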

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

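The signal on chromosome Y described here was looked for only after the lists had been read, and the tests of the H3K27me3 and H3K4me3 patterns were set out after the region numbers were known but before their own results, and the counts without replicates of H3K27me3 were added later.

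Chromosome Y was left out of the comparisons, and regions called there drew attention as signal in unused data. The lists held 21 H3K27ac, 38 H3K4me3, 16 RNAPII Ser5P and 4 H3K27me3 regions on it, and none of H3K4me1. Most lay at 3 places in mm9, at 345751 to 348100 in 22 libraries, at 580701 to 582300 in 18 libraries and at 622026 to 623050 in 16 libraries. Their relation to stage was not tested.

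Replicate 3 of H3K27me3 had few regions in ESC (3252) and in CM (2929), against 9373 in ESC replicate 2 and 11925 in CM replicate 2. Calls scattered at random were excluded, since 85.5% of the regions in ESC and 96.9% in CM overlapped another library of their stage, at least 135 times the share after random placement. A weak or shallow library that detects the strongest sites may account for the low numbers, as the regions of replicate 2 that replicate 3 also found had 1.61 and 1.63 times the median peak height of those it missed. Without these libraries, H3K27me3 gained 2048 and lost 2429 regions from ESC to CM, and ESC had 3568 bivalent regions, with a single ESC library of the mark left. No biological difference between replicates of a stage is given by the labels, so none was tested.

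H3K4me3 had more regions in ESC than at later stages, with a ratio of 1.97. Short calls near the threshold cannot be told apart from a real difference, since the ratio was 1.35 for regions of at least 1 kb and 2.91 for those under 500 bases, between the limits set for either reading. Weaker ESC libraries that could pick up sites of other marks cannot be told apart either, as 36% of the lost regions overlapped H3K4me1 or H3K27ac in every ESC library, between the limits set. The share was 77.5% in any ESC library, but without the same share for kept regions it decides nothing. Per ESC library, H3K27ac was called at a mean of 50.3% of the lost and 73.5% of the kept regions. For H3K4me1 the means were 34.96% and 43.9%, so such overlap was not particular to the lost regions. The median ratio of target to background was 9.47 and 9.42 in ESC against 16.3 to 23.0 in the 6 later libraries. That ratio is a median over called regions, so it depends on which regions were called and does not decide how strong the libraries were. The difference in stage, from stem cells to differentiated cells, stays open and untested against these explanations.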

How the results depend on the processing

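The alternatives without ESC replicate 1 of H3K4me1, without ESC replicate 3 and CM replicate 3 of H3K27me3, with earlier H3K4me1 in at least 1 library and with earlier active regions left out were chosen after the data were seen, and the others before the data were examined, with the nearest H3K4me3 region standing in for the nearest start site. Of 236 values of main results under an alternative, 145 kept their direction and side of the threshold or stayed within 1.5 times the count, as did 93 of 231 others. Of these, 16 and 47 counts were identical because the setting left their libraries or their rule as they were (a majority of 2 libraries is both), and they say nothing about stability, nor do the odds ratios from MES to CP and from CP to CM without ESC replicate 1 of H3K4me1. No test on number or covered length passed under any alternative run, and clustering of H3K4me1 and H3K27ac passed under all that were run. Where no cause is given, the cause was not tested.

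An equal number of top regions, by construction fewer regions, gave 4608 H3K4me1 regions lost and 23873 stage-concordant, 6775 H3K27ac lost, 2199 H3K4me3 gained, 3349 lost and 6971 concordant, 1597 RNAPII Ser5P gained, 5245 lost and 9074 concordant, 254 H3K27me3 lost and 1183 concordant, and 744 bivalent regions. The odds ratio of earlier H3K4me1 from ESC to MES turned to 0.720 (Fisher exact p = 0.0009), and that near gained H3K4me3 to 0.987 (p = 0.855). Leaving out regions under 500 bases gave 6419 and 3905 H3K4me1 regions gained and lost, 3739 and 5965 of H3K27ac, 315 and 7510 of H3K4me3, 440 and 12194 of RNAPII Ser5P, and 5 and 9 of H3K27me3, with 63 bivalent regions, 4 of them with H3K4me3 only in CM.

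Without ESC replicate 3 and CM replicate 3 of H3K27me3, 2048 regions were gained, 2429 lost and 6320 concordant, and 3568 were bivalent, 664 with H3K4me3 only in CM. Without ESC replicate 1 of H3K4me1, the odds ratio from ESC to MES was 0.953. A majority of libraries gave 29475 and 26200 H3K4me1 regions gained and lost and 2046 and 275 of H3K27me3. With the share of the smaller set, clustering had adjusted p of 0.0119 for H3K4me3 and 0.000487 for H3K27me3. Earlier H3K4me1 in at least 1 library gave odds ratios of 1.61 from ESC to MES, 1.08 from CP to CM and 1.04 from ESC to CM. With earlier active regions left out, those of the last 2 were 0.992 and 0.893.

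The labels tie replicate numbers to no shared batch, and they were not taken to pair the samples, since same-number correlations of deviations from the stage mean were over 0.1 in only 6 of 18 H3K4me1, 0 of 12 H3K27ac, 4 of 12 H3K4me3, 2 of 6 RNAPII Ser5P and 2 of 15 H3K27me3 pairs. They were positive in all pairs of H3K4me1, H3K27ac and RNAPII Ser5P, and their mean exceeded that of other pairs in 4 of 5 marks (0.0707 against -0.0346 for H3K4me1). Every library correlated best with its own number for H3K27ac (8 of 8) and RNAPII Ser5P (6 of 6), and 6 of 12 did for H3K4me1, 2 of 8 for H3K4me3 and 0 of 11 for H3K27me3, a hint from the data and not from the design. With 2 libraries per stage, deviations from the stage mean mirror each other. For H3K27ac, H3K4me3 and RNAPII Ser5P, the comparison with other pairs therefore only restates the same-number correlations. As a block, the replicate numbers gave adjusted p for clustering of 0.0417 for H3K4me3 and RNAPII Ser5P and 0.0304 for H3K27me3 (exact permutation). They also gave 4239 RNAPII Ser5P regions gained and 62557 concordant, 263 H3K27me3 lost, 3683 bivalent regions and 1033 with H3K4me3 only in CM, both from number 2 alone, and 3538 active in CP. The odds ratio of earlier H3K4me1 from ESC to CM was 0.886 (Fisher exact p = 0.0962).

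Leaving out each replicate, which asks for fewer matching calls, gave these ranges. H3K4me1 gained 14185 to 21109, lost 11644 to 19003 and had 55729 to 62302 concordant. H3K27ac gained 13862 to 21337, lost 20287 to 56277 and had 59249 to 110327 concordant. H3K4me3 gained 2089 to 4062, lost 23357 to 32533 and had 28355 to 44562 concordant. RNAPII Ser5P gained 4312 and had 63272 concordant. H3K27me3 gained 204 to 2048, lost 271 to 2433 and had 4131 to 10769 concordant, and its clustering had adjusted p of 0.0238 to 0.381, with 0.352 in the opposite direction without replicate 1. Bivalent regions numbered 1101 to 3568, and those with H3K4me3 only in CM 161 to 664. Active regions numbered 2339 to 6844 in ESC, 3077 to 7903 in MES, 3496 to 4600 in CP and 5020 to 8481 in CM. Odds ratios of earlier H3K4me1 were 0.962 to 1.03 from ESC to MES, 0.669 to 0.931 from CP to CM and 0.751 to 0.898 from ESC to CM.

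The number of regions has no value with an equal number of top regions. Leaving out replicate 1 or 2 left no test for H3K27ac and H3K4me3, with 1 library per stage, and no ESC library of RNAPII Ser5P without replicate 2. Windows of start sites, distance to start sites and gene lists were not run. Depth is unknown, so a region missing from a list was not detected there, which does not show that the mark was absent.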

Other observations

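The comparison of marks that changed together, the odds ratio with earlier active regions left out, the H3K27me3 domains, the counts without ESC replicate 3 and CM replicate 3 of H3K27me3 and the regions on the mitochondrial genome were chosen after the data were seen.

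Marks moved together between ESC and CM. Of the 11023 H3K4me1 regions gained, 3279 (29.7%) also gained H3K27ac and 43 lost it, and of the 8902 lost, 4196 (47.1%) lost H3K27ac and 8 gained it. Of the 922 H3K4me3 regions gained, 332 (36%) gained H3K27ac and 5 lost it. The gained H3K4me3 regions have the mark at 0% in ESC and 100% in CM by the way they were chosen. In between, it was called at 18.3 ± 3.99% of them in MES and 40.5 ± 18.0% in CP (SD, n = 2 each), where the libraries had 27.8% and 53.3%. H3K27ac was called at 5.04 ± 4.99% in ESC, 21.3 ± 7.29% in MES, 28.2 ± 4.91% in CP and 47.6 ± 0.614% in CM (SD, n = 2 each).

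H3K27me3 changed mostly in the opposite direction to H3K27ac and RNAPII Ser5P where both changed. Of the 206 H3K27me3 regions gained, 58 (28.2%) lost H3K27ac and 0 gained it, and 59 (28.6%) lost RNAPII Ser5P and 1 gained it. Of the 167 lost, 17 (10.2%) gained H3K27ac and 0 lost it, and 36 (21.6%) gained RNAPII Ser5P and 2 lost it. Of the 620 H3K27me3 regions kept, 4.52% lost H3K27ac and 6.61% lost RNAPII Ser5P by the same rule. H3K27ac per library also went from 42.7 ± 47.6% of the kept regions in ESC to 12.7 ± 0.684% in CM, against 54.9 ± 27.5% and 7.28 ± 2.06% of the gained regions (SD, n = 2 each), so a lower share in CM was not particular to the gains. The Fisher exact tests gave adjusted p of 4.49e-17 for H3K27ac and 4.81e-23 for RNAPII Ser5P over 20 tests, with regions that are not independent. Without ESC replicate 3 and CM replicate 3 of H3K27me3, 282 of 2048 gained regions (13.8%) lost H3K27ac and 7 gained it, and 181 of 2429 lost regions (7.45%) gained H3K27ac and 8 lost it. H3K27me3 and H3K4me3 showed no association over all libraries (adjusted p = 1 among changed H3K27me3 regions, Fisher exact). Without those libraries, 106 of the gained H3K27me3 regions lost H3K4me3 and 11 gained it. Of the lost H3K27me3 regions, 96 lost H3K4me3 and 68 gained it (adjusted p = 1.43e-09, Fisher exact). H3K4me3 losses thus outnumbered gains in both groups, and among changed H3K4me3 regions the association was absent (adjusted p = 0.664, Fisher exact).

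The stage-concordant regions were compared with 100 groupings of the libraries, the real one included. Chance can be excluded for H3K4me1, with 37961 regions against at most 23712 in the others, and for H3K27ac, with 29731 against 24781, where 1 of the 100, the real one, reached the count. For RNAPII Ser5P, 1 of the 100 reached the count too, but 39713 stood against 39610, and for H3K4me3, 3 of the 100 reached 18916, the highest other giving 19429, with the ESC libraries kept together in the other groupings that did. The share was under 0.05 for both of these marks, but chance is not excluded for grouping by all 4 stages. Their overlap between libraries did not pass its own test, and RNAPII Ser5P in ESC rests on a single library. Groupings that kept the ESC libraries together did as well for H3K4me3, so its count speaks only to ESC against the later stages. For H3K27me3, 6 of the 100 reached 3243, the highest other giving 4945, so chance is not excluded.

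For gains and losses between stages with 3 libraries each, the 10 splits are too few for a share under 0.05. H3K4me1 changed at 17443 regions from ESC to MES (highest other 2943), 7768 from MES to CP (5434), 7694 from CP to CM (2707) and 19925 from ESC to CM (1156), with 1 of 10 splits as large in each. H3K27me3 changed at 494 regions from MES to CP (highest other 755) and 944 from CP to CM (1037), with 2 of 10 splits as large. With 2 ESC libraries, it changed at 1238 regions from ESC to MES (highest other 1927, 2 of 10 splits as large) and at 373 from ESC to CM (1788, 4 of 10). H3K4me3, with 3 splits, changed at 809 regions from MES to CP (highest other 1411) and 949 from CP to CM (1423), with 2 of 3 splits as large in each, so these splits too are too few.

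With earlier H3K4me1 asked for in every library, newly active distal regions did not have more of it than regions with H3K4me1 alone, and from MES to CP they had less. With at least 1 library, the odds ratio from ESC to MES was 1.61, without stratifying by length. The length of the regions would have raised the share at newly active ones, which were longer (median 1875 against 1075 bases in CP). After stratifying by length, the odds ratio fell in each of the 3 steps, from 1.02 to 0.914 from ESC to MES and from 0.859 to 0.651 from CP to CM. From MES to CP it fell from 0.584 to 0.384, the lowest, so length does not account for the lower share there. No interval was computed for these ratios. The test was set out for an excess, and with none when every library was asked for, it decides nothing about an excess. Regions active in MES, kept among the regions with H3K4me1 alone, were excluded as the whole cause of the lower share, since the odds ratio was 0.682 without them.

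RNAPII Ser5P in CM replicate 2 had regions on the mitochondrial genome at 26 to 6550 and 10851 to 16400, with peak heights of 332 and 338 against a median of 48 in that library. H3K27me3 in CM replicate 2 had one with a height of 190 against a median of 28. Regions of H3K27me3 within 5 kb of each other formed 247 and 55 domains of at least 10 kb in the ESC libraries, 245 to 592 in MES, 336 to 1412 in CP and 59 to 624 in CM.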
